A study of Mus musculus with 6 samples.

How the data were processed

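The data are gene counts from HL-1 cells, a mouse atrial cardiomyocyte line, transfected with an siRNA against the circular RNA Circ-INSR or with a scrambled control siRNA. There were 2 groups of 3 libraries. The labels give 100 nM for the Circ-INSR siRNA. Per the labels' protocols, RNA was taken with a miRNeasy kit, mRNA was selected by its poly(A) tail, and directional libraries were made with an NEBNext Ultra II kit. Poly(A) selection favours linear mRNA, so a circular RNA is not measured by these libraries.

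The deposited values are raw counts per Ensembl gene, 1 column for each library, with no normalization. The submitters' processing notes name the mouse build mm10 and the tools bcl2fastq, FastQC 0.11.4, Trim Galore, STAR 2.5.0c, featureCounts 1.6.4, StringTie 1.3.5 and MultiQC 1.7, with no role or order for any of them. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Counts of genes that overlap on opposite strands, or that share reads with near-identical copies, are therefore uncertain. In every file genes with a count of 2 outnumbered genes with a count of 1, and genes with a count of 4 outnumbered those with 3, which is the pattern left when both mates of a read pair are counted. Such counts overstate the independent fragments, and the tests were repeated with counts halved.

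The files list 38087 gene IDs, of which 12109 were at 0 in all libraries. Symbols, positions and exon models came from GENCODE mouse release M21, which is on the same build, and 36308 IDs (95.33%) were found in it. No gene of the mitochondrial genome was among the IDs, so mitochondrially encoded mRNAs were not analysed here. Total counts per library ran from 60024750 to 77037474, and 3 counts corresponded to between 0.0389 and 0.0500 CPM (counts scaled to a common library size).

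Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which kept 16666 genes, and libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.983 to 1.03. The robust quasi-likelihood F-test was applied with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. The common biological coefficient of variation was 6.09%. CPM values are TMM-scaled. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of F. On simulated counts with the means and depths of these libraries and 200 changed genes among 16666, the same steps recovered 76% of the genes changed by 2-fold and 62% of those changed by 1.3-fold, with 11 false calls among 149. Far more genes, 9495, were called in the data, so these rates may not hold there.

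Gene lists for 36 pathways, complexes and cell types were fixed before the data were examined, and 35 had members that could be tested. The list of mRNAs encoded by mitochondrial DNA matched 0 of its 13 members. Lists were tested with camera (limma 3.58.1) on log2 CPM with voom weights and a preset inter-gene correlation of 0.01, adjusted over the 35 lists. The same test with an estimated correlation, and fry, were run beside it. The genes named were also chosen by a rule fixed beforehand. It takes Insr and Ssbp1, then the 10 largest rises and the 10 largest falls among genes past the threshold with an average log2 CPM of at least 1, separate groups and a name that is not that of a predicted gene. It then takes up to 4 members of each list with the smallest adjusted p, or 2 of the highest expressed where none passed. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

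Alternatives were other scalings (relative log expression, upper quartile, total counts), other filters on low counts, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom and glmTreat. Halved counts, libraries thinned to the lowest total, and removal of a trend on exonic length and GC content in each library were added after the data were seen. Sites in 3' UTRs were scored with numpy 2.4.6 in Python 3.11.15. The longest annotated 3' UTR of each protein-coding gene (at least 50 bases) was searched for all 16384 words of 7 bases. The log2 fold change, limited to between -2 and 2, was regressed on the presence of each word after removal of terms for length, GC content and expression. Terms for the shares of pairs of neighbouring bases, alone and multiplied by length, were added in a further run after the scores were seen. In shuffled data with a fall of 0.2 given to genes with a chosen word, that word had the lowest score of all. That fall was larger than the differences of -0.0981 and -0.103 later found for the words ACACTTT and CTGGTAT. Recovery of a word at the size found was not tested.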

Results

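Messenger RNA was profiled in HL-1 cells, a mouse atrial cardiomyocyte line, after transfection with 100 nM siRNA against Circ-INSR, a circular RNA of the insulin receptor gene, or with a scrambled control siRNA. Each group had 3 libraries. Total counts lay between 60024750 and 62523602 in the control group and between 68468620 and 77037474 in the Circ-INSR siRNA group, with a ratio of the means of 1.19. In an exact two-sided permutation test of the totals p was 0.1, which is the smallest p that 3 against 3 libraries can give. The 10 most abundant genes held 2.77 ± 0.0574% of the counts in control libraries and 3.52 ± 0.0155% in Circ-INSR siRNA libraries. The first principal component of log2 CPM held 71.2% of the variance and separated the groups. Control replicate 3 stood apart from the other controls, with a chi-square per gene of 31.7 and 22.1 against them, compared with 7.06 between control replicates 1 and 2. The longest 10% of genes by exonic length, with at least 9219 bases, had a median log2 deviation of -0.13 from the mean of all libraries there, and 0.03 and 0.04 in control replicates 1 and 2. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

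The comparison asks which mRNAs differ in HL-1 cells when Circ-INSR is targeted. The 10 largest rises included Casq1 and Hrc, which encode calcium-binding proteins of the sarcoplasmic reticulum, and Csrp3, a Z-disc protein gene, with log2 fold changes of 2.71, 2.67 and 2.39 (SE 0.09, 0.11 and 0.06). Of p53 target genes 28 of 34 were lower and 0 higher, and of NRF2 targets and antioxidant genes 21 of 33 were lower. Of genes of G2/M and mitosis 41 of 57 were higher, and of cholesterol synthesis genes 23 of 33. Camera with a preset correlation called these 4 lists, with adjusted p from 9.66e-12 to 0.000341, and 0 of them held with an estimated correlation, at adjusted p from 0.274 to 0.421. Of 16666 genes tested, 4750 were higher and 4745 lower after Circ-INSR siRNA (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among them 490 were higher and 928 lower by an absolute log2 fold change of at least 1. These larger changes numbered 277 and 585 when genes needed 1 CPM in 3 libraries, and 171 and 312 when glmTreat tested the size itself. The libraries of the groups did not overlap for 10545 genes (63.3%), where chance gives 10%.

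**Figure D1:**
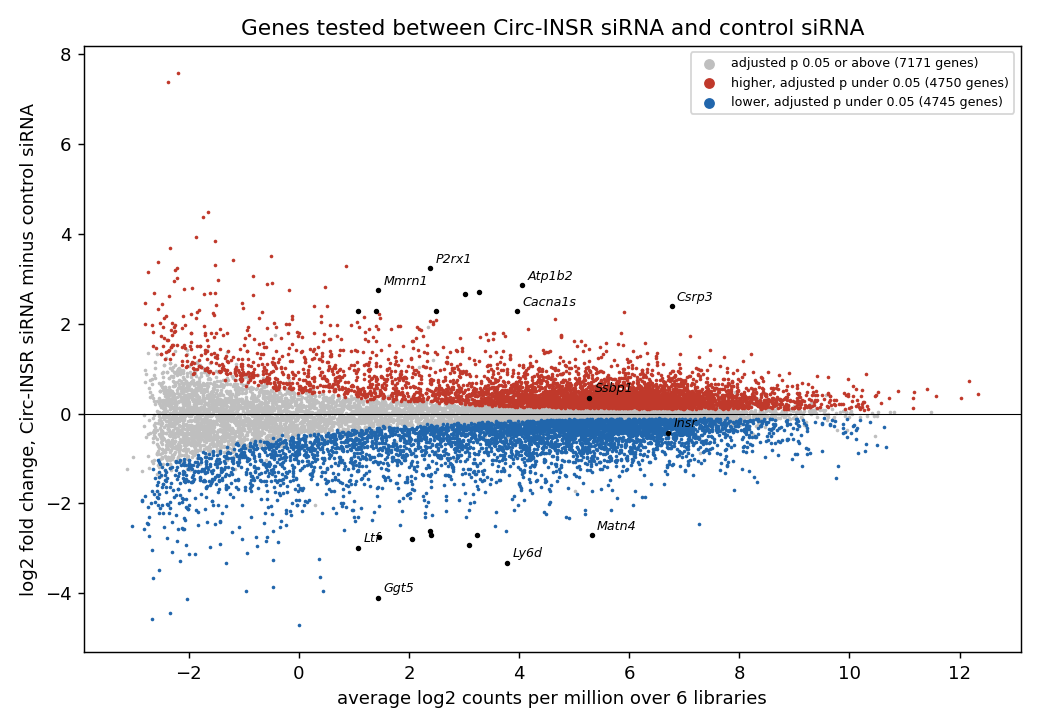
Each point is 1 of the 16666 genes tested, with its average log2 CPM over 6 libraries on the x axis and its log2 fold change (Circ-INSR siRNA minus control siRNA) on the y axis. Red points are the 4750 genes higher and blue points the 4745 lower at adjusted p under 0.05, and black points are Insr, Ssbp1 and the 10 largest rises and falls, some of them named.

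Insr, the insulin receptor gene that hosts the circular RNA (ENSMUSG00000005534, mm10 chromosome 8, 3122061 to 3279617, minus strand), fell by 0.43 on the log2 scale (SE 0.07; edgeR adjusted p = 0.000393). It had 120.1 ± 14.2 CPM in control and 89.2 ± 0.0183 CPM in Circ-INSR siRNA libraries (SD, n = 3 each). Control replicate 3 had 103.8 CPM against 129.0 and 127.6 CPM in the other controls. Gene counts from poly(A)-selected RNA do not tell circular from linear RNA, so this value does not measure the knockdown of Circ-INSR. Ssbp1, which encodes the mitochondrial single-stranded DNA binding protein (ENSMUSG00000029911, chromosome 6, 40471352 to 40484700, plus strand), rose by 0.36 (SE 0.07; edgeR adjusted p = 0.000603), from 33.8 ± 3.15 to 43.3 ± 1.72 CPM.

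The largest rise was that of P2rx1, an ATP-gated cation channel, from 0.970 ± 0.163 to 9.14 ± 0.426 CPM (SD, n = 3 each), a log2 fold change of 3.23 (SE 0.12). Atp1b2, a beta subunit of the sodium pump, rose by 2.85 (SE 0.07) and Mmrn1, encoding multimerin, by 2.75 (SE 0.15). Casq1, a calcium-binding protein of the sarcoplasmic reticulum, rose from 2.51 ± 0.256 to 16.4 ± 0.892 CPM, and Hrc, another of that compartment, from 2.15 ± 0.362 to 13.6 ± 0.231 CPM. Csrp3, the muscle LIM protein of the Z-disc, rose from 34.97 ± 1.51 to 182.7 ± 11.1 CPM, a log2 fold change of 2.39 (SE 0.06). Cacna1s, the pore subunit of the skeletal muscle L-type calcium channel, rose by 2.27 (SE 0.11), as did Lipg, the endothelial lipase (SE 0.11). Bhmt, betaine-homocysteine methyltransferase, and Rspo2, a secreted activator of Wnt signalling, rose by 2.30 (SE 0.14) and 2.29 (SE 0.17). Adjusted p of these 10 genes lay between 4.46e-10 and 4.38e-07 in the edgeR test.

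The largest fall was that of Ggt5, a gamma-glutamyltransferase, from 5.28 ± 0.546 to 0.304 ± 0.0589 CPM (SD, n = 3 each), a log2 fold change of -4.10 (SE 0.17). Ly6d, a membrane-anchored surface protein, fell from 25.3 ± 1.11 to 2.53 ± 0.1502 CPM, a log2 fold change of -3.32 (SE 0.08). Ltf, which encodes lactoferrin, changed by -2.98 (SE 0.22) and Vwa7 by -2.93 (SE 0.10). Matn4, a matrilin of the extracellular matrix, fell from 69.4 ± 5.20 to 10.6 ± 1.39 CPM. Sprr1a changed by -2.78 (SE 0.12), the receptor gene Gpr151 by -2.74 (SE 0.15) and Ankrd35 by -2.71 (SE 0.09). The transporter gene Slc22a18 changed by -2.70 (SE 0.14) and the aldehyde dehydrogenase gene Aldh3a1 by -2.61 (SE 0.15). Adjusted p of these 10 genes lay between 3.78e-10 and 4.67e-07 in the edgeR test.

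**Figure D2:**
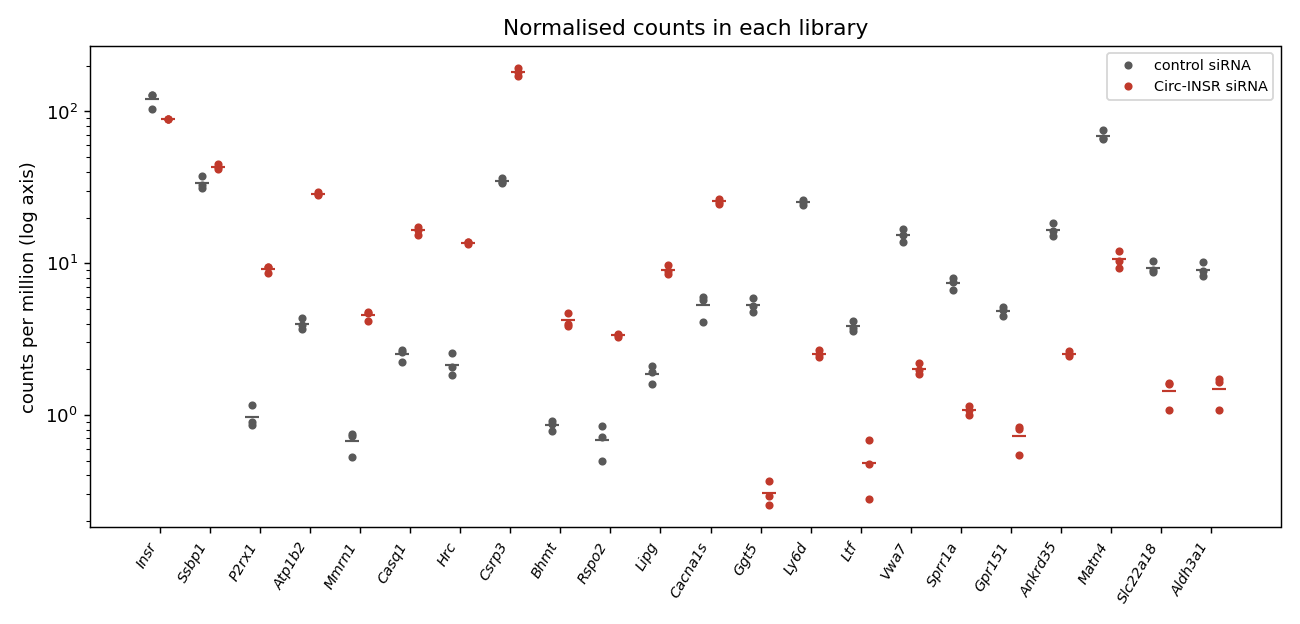
Points show TMM-scaled CPM in each of the 6 libraries on a log axis for Insr, Ssbp1 and the 10 largest rises and falls, in grey for control siRNA and red for Circ-INSR siRNA, with a bar at each mean. For P2rx1 the means were 0.970 and 9.14 CPM, and for Ggt5 5.28 and 0.304 CPM.

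Of the 35 lists tested, camera with a preset correlation called 9 higher and 7 lower at adjusted p under 0.05. With an estimated correlation 0 held, and 4 of the 35 had an unadjusted p under 0.05. For some lists that lost their call the estimate was above the preset 0.01, such as 0.116 for p53 targets and 0.863 for ribosomal proteins. For others it was below, at -0.00290 for autophagy and lysosome genes, -0.0193 for BCL2 family genes, -0.0231 for NF-kB targets, 0.00274 for mitochondrial regulators and 0.00675 for chaperones. A higher correlation is not why those calls ended, so such a loss does not by itself show that members move together. For autophagy and lysosome genes, camera's unadjusted p was 0.00186 with the preset correlation and 0.0212 with the estimated one. The directional test of fry, which does not compare a list with other genes, called 21. Among p53 target genes 28 of 34 fell and 0 rose, the same counts adjusted over the list alone, with a median log2 fold change of -0.67 (camera adjusted p = 9.66e-12; adjusted p = 0.274 with an estimated correlation). Gdf15, a stress-induced secreted factor, fell from 83.7 ± 3.58 to 18.9 ± 1.58 CPM. Ephx1, the microsomal epoxide hydrolase, fell from 367.1 ± 14.6 to 113.4 ± 5.64 CPM, Mdm2, the ubiquitin ligase of p53, from 372.3 ± 5.50 to 158.9 ± 3.92 CPM, and Dcxr from 81.9 ± 4.16 to 31.4 ± 1.35 CPM. Other lists held 9 of the 34 members. Of BCL2 family and caspase genes 17 of 32 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.00942; adjusted p = 0.274 with an estimated correlation). The median was -0.265 for all 32, of which 5 were also in other lists. The 27 in this list alone had a median of -0.116, with 13 lower and 5 higher. Mlkl, the effector of necroptosis, changed by -1.03 (SE 0.05), Bnip3 by -0.85 (SE 0.08), Bbc3 by -0.66 (SE 0.07) and Cflar by -0.62 (SE 0.06).

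Immediate early genes fell in 17 of 35 cases and rose in 6, also when adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.543 with an estimated correlation). Fosl1 changed by -2.25 (SE 0.11), Junb by -1.38 (SE 0.04), Btg2 by -1.36 (SE 0.05) and Atf3 by -1.33 (SE 0.07). Without control replicate 3, which stood apart, the camera adjusted p of that list was 0.0505, and with the trend on length and GC removed it was 0.139. Of NF-kB targets, cytokines and chemokines 16 of 26 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.274 with an estimated correlation). They included Lcn2 (-3.85, SE 0.32), Cxcl16 (-1.65, SE 0.12), the cytokine gene Lif (-1.52, SE 0.06) and the adhesion molecule gene Icam1 (-0.93, SE 0.05). Of NRF2 targets and antioxidant genes 21 of 33 fell and 4 rose, with 21 and 5 adjusted over the list alone (camera adjusted p = 0.000341; adjusted p = 0.310 with an estimated correlation). Hmox1, heme oxygenase, fell from 82.9 ± 1.89 to 34.2 ± 1.23 CPM, Osgin1 changed by -2.20 (SE 0.10), Gstm1, which has close paralogs, by -1.50 (SE 0.06) and Srxn1 by -0.94 (SE 0.05). Of autophagy and lysosome genes 21 of 41 fell and 5 rose, with 22 and 5 adjusted over the list alone (camera adjusted p = 0.00942; adjusted p = 0.274 with an estimated correlation). The cathepsin gene Ctsd fell from 1790 ± 47.5 to 1101 ± 37.2 CPM, Ctsb changed by -0.79 (SE 0.04), Gabarapl1 by -0.74 (SE 0.05) and the autophagy receptor gene Sqstm1 by -0.56 (SE 0.04).

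Genes of G2/M and mitosis rose in 41 of 57 cases and fell in 5, also when adjusted over the list alone (camera adjusted p = 1.07e-06; adjusted p = 0.310 with an estimated correlation). Plk1, a mitotic kinase, rose by 0.76 (SE 0.04) and Ccnb1, which encodes a mitotic cyclin, by 0.72 (SE 0.04). Gtse1, also a p53 target, changed by -0.80 (SE 0.05) and the tubulin gene Tubb4b by -0.64 (SE 0.04). Of genes of G1/S and DNA replication 22 of 45 rose and 8 fell, with 23 and 8 adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.421 with an estimated correlation). Nasp, a histone chaperone, rose by 0.70 (SE 0.05), Ung by 0.47 (SE 0.05), Pold3 by 0.45 (SE 0.04) and the helicase subunit gene Mcm4 by 0.36 (SE 0.04). Cytosolic ribosomal protein genes, which share reads with processed pseudogenes, rose in 33 of 77 cases and fell in 5, with 32 and 5 adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.860 with an estimated correlation). Rps20 rose by 1.32 (SE 0.05), Rpl37 by 0.74 (SE 0.05), Rps29 by 0.66 (SE 0.05) and Rps13 by 0.40 (SE 0.06), while the camera adjusted p of the list was 0.0671 with total-count scaling and 0.0747 without control replicate 2. Of replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 1 of 22 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.759). Hist1h2bc rose by 0.36 (SE 0.06), Hist2h2aa1 changed by -1.01 (SE 0.12) and Hist1h1e by -0.78 (SE 0.17).

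Sarcomere and Z-disc genes rose in 21 of 35 cases and fell in 8, also when adjusted over the list alone (camera adjusted p = 0.0170; adjusted p = 0.421 with an estimated correlation). Synpo2l rose from 63.9 ± 2.14 to 210.9 ± 12.4 CPM, Tnni1, the slow skeletal troponin I, from 96.1 ± 5.10 to 256.4 ± 11.2 CPM, and Tnnc1, the cardiac and slow troponin C, from 42.4 ± 2.04 to 103.8 ± 4.19 CPM. Of cardiac transcription factor genes 13 of 26 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.345 with an estimated correlation). Tbx18 rose by 1.26 (SE 0.05), Gata6 by 1.19 (SE 0.06), and Nr2f1 and Nr2f2, which mark atrial identity, by 0.77 (SE 0.05) and 0.72 (SE 0.05). Calcium handling, ion channel and gap junction genes went both ways, with 12 of 37 higher and 13 lower, also when adjusted over the list alone (camera adjusted p = 0.743). Casq1 rose by 2.71 (SE 0.09) and Hrc by 2.67 (SE 0.11), and Hcn2, a pacemaker channel gene, rose by 1.12 (SE 0.06) and Trdn, which encodes triadin, by 0.73 (SE 0.05). Of natriuretic peptide and hypertrophy genes 12 of 25 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.654), with Bdnf higher by 1.15 (SE 0.09), Edn1 by 1.10 (SE 0.08) and Ccn2 by 0.71 (SE 0.05), and Gdf15 lower (-2.15, SE 0.06). Extracellular matrix and TGF-beta genes rose in 15 of 37 cases and fell in 11, also when adjusted over the list alone (camera adjusted p = 0.588). Thbs1 rose by 1.74 (SE 0.06) and Tgfb2 by 0.72 (SE 0.05), whereas Thbs2 changed by -0.83 (SE 0.06) and Mmp14 by -0.67 (SE 0.05).

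Mitochondrial ribosomal protein genes rose in 43 of 77 cases and fell in 8, also when adjusted over the list alone (camera adjusted p = 0.00142; adjusted p = 0.850 with an estimated correlation). Mrps16 rose by 0.65 (SE 0.05), Mrpl37 by 0.60 (SE 0.04), Mrpl3 by 0.59 (SE 0.04) and Mrpl48 by 0.53 (SE 0.04). Nuclear-encoded subunits of complex I fell in 19 of 36 cases and rose in 8, also when adjusted over the list alone (camera adjusted p = 0.0404; adjusted p = 0.860 with an estimated correlation). Ndufb4 changed by -0.87 (SE 0.07), Ndufa5 by -0.66 (SE 0.06) and Ndufa13 by -0.45 (SE 0.04), while Ndufb10 rose by 0.56 (SE 0.05). The camera adjusted p of complex I was 0.146 without control replicate 3, 0.0869 without Circ-INSR siRNA replicate 2, 0.0526 with the filter of 1 CPM and 0.171 with the trend on length and GC removed. Subunits of complexes II to V fell in 17 of 41 cases and rose in 11, with 18 and 12 adjusted over the list alone (camera adjusted p = 0.743), among them Cox6a1 at -0.40 (SE 0.05), Sdhd at 0.43 (SE 0.06), Atp5g1 at 0.39 (SE 0.05) and Uqcrc2 at 0.28 (SE 0.04). Of regulators of mitochondrial fusion, fission, mitophagy and biogenesis 17 of 27 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.310 with an estimated correlation; 0.0632 with the trend on length and GC removed). The genes of both mitofusins, which drive fusion of the outer membrane, moved apart, with Mfn1 at 122.8 ± 1.55 against 58.2 ± 0.834 CPM and Mfn2 at 134.9 ± 1.204 against 303.8 ± 27.0 CPM in control. Gabpa rose by 0.69 (SE 0.05) and Bnip3l, a mitophagy receptor gene, changed by -0.79 (SE 0.06). Of mitochondrial DNA maintenance genes, a list that holds Ssbp1, 10 of 24 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.353). Lig3 rose by 0.59 (SE 0.06) and the polymerase gene Polg by 0.51 (SE 0.05), and the protease gene Lonp1 changed by -0.53 (SE 0.05) and Top1mt by -0.46 (SE 0.06).

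Cholesterol synthesis and SREBP2 target genes rose in 23 of 33 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 2.90e-05; adjusted p = 0.421 with an estimated correlation). Hmgcs1 rose from 113.7 ± 6.94 to 209.6 ± 12.7 CPM, Dhcr7 by 0.73 (SE 0.05) and the epoxidase gene Sqle by 0.56 (SE 0.04). Genes of the tricarboxylic acid cycle rose in 11 of 22 cases and fell in 5, with 12 and 6 adjusted over the list alone (camera adjusted p = 0.149, and 0.0394 with no filter on low counts). Pdha1, a subunit of pyruvate dehydrogenase, rose from 468.9 ± 4.61 to 744.5 ± 8.86 CPM, and Suclg2, Cs and Dlst rose by 0.46, 0.42 and 0.38 (SE 0.04 each). Fatty acid oxidation genes rose in 12 of 28 cases and fell in 9, also when adjusted over the list alone (camera adjusted p = 0.588). Hadhb rose by 1.02 (SE 0.06) and Acadm by 0.57 (SE 0.04), and Pdk4 changed by -0.79 (SE 0.04) and Slc27a1 by -0.64 (SE 0.06). Glycolysis genes rose in 11 of 25 cases and fell in 7, with 11 and 8 adjusted over the list alone (camera adjusted p = 0.550). Pfkfb3 rose by 1.01 (SE 0.06) and the lactate transporter gene Slc16a1 by 0.60 (SE 0.05), and Pfkfb2 changed by -0.81 (SE 0.05) and Eno3 by -0.53 (SE 0.04).

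Of genes of the insulin receptor and its signalling chain 12 of 33 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.134, and 0.0342 with no filter on low counts). Irs1, an adaptor of the receptor, rose from 20.3 ± 2.45 to 40.96 ± 1.02 CPM, the glucose transporter genes Slc2a1 and Slc2a4 by 0.70 (SE 0.04) and 0.53 (SE 0.05), and the kinase gene Pdpk1 changed by -0.57 (SE 0.05). Cytosolic and mitochondrial chaperone genes rose in 17 of 29 cases and fell in 6, also when adjusted over the list alone (camera adjusted p = 0.0328; adjusted p = 0.310 with an estimated correlation). Hspd1 rose from 739.4 ± 28.4 to 1261 ± 3.62 CPM, Hspa8 by 0.47 (SE 0.03) and Hsp90ab1 by 0.39 (SE 0.03), and Cryab changed by -0.51 (SE 0.04), while the camera adjusted p of the list was 0.0563 with total-count scaling and 0.0670 with the filter of 1 CPM. Endoplasmic reticulum chaperone and unfolded protein response genes rose in 10 of 26 cases and fell in 9, with 10 and 10 adjusted over the list alone (camera adjusted p = 0.814), including Calr at 0.41 (SE 0.04), Manf at 0.40 (SE 0.05), Ero1l at -0.55 (SE 0.05) and Herpud1 at -0.37 (SE 0.05). Of small RNA processing and silencing genes 12 of 25 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0979, with 0.0225 under no filter and 0.0448 without control replicate 2). Dicer1 rose by 0.80 (SE 0.06), Dhx9 by 0.54 (SE 0.04) and Tarbp2 by 0.40 (SE 0.05), and the RNA editing enzyme gene Adarb1 changed by -1.05 (SE 0.07). Interferon-stimulated genes passed in 11 of 51 cases only, 5 higher and 6 lower, with 2 and 6 adjusted over the list alone (camera adjusted p = 0.556). Psmb9 changed by -0.91 (SE 0.09), Tap1 by -0.85 (SE 0.06), Irf1 by -0.58 (SE 0.06) and Psmb8 by -0.46 (SE 0.07). Irf7, chosen after its values were seen, had 15.7 CPM in Circ-INSR siRNA replicate 3 against 43.1 and 55.6 CPM in the other libraries of that group.

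**Figure D3:**
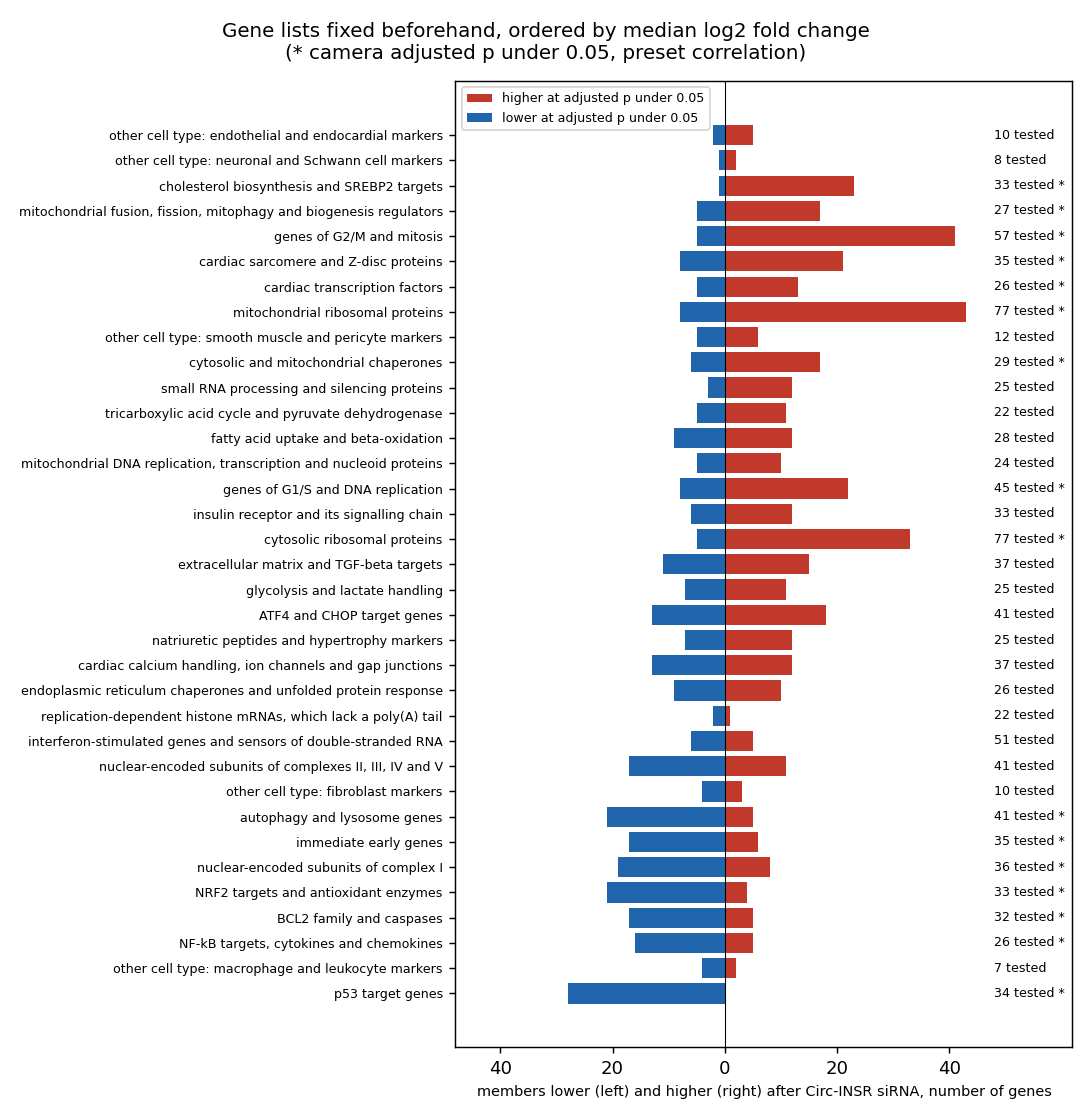
Bars give, for each of the 35 gene lists tested, the number of members lower (blue, left) and higher (red, right) at edgeR adjusted p under 0.05, with the number tested at the right and a star where the camera adjusted p with preset correlation was under 0.05. The p53 target list lies at the bottom, with 28 of 34 members lower and 0 higher.

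HL-1 is a single cell line, and markers of other cell types were tested to describe the libraries. Endothelial and endocardial markers rose in 5 of 10 cases and fell in 2 (camera adjusted p = 0.146), with Kdr at 71.7 ± 2.49 against 24.2 ± 1.45 CPM in control, Tek at 1.45 (SE 0.10) and Npr3 at 1.17 (SE 0.05) higher, and Plvap at -1.24 (SE 0.09). Smooth muscle and pericyte markers rose in 6 of 12 cases and fell in 5 (camera adjusted p = 0.743), with Acta2 at 5793 ± 126 against 3475 ± 49.6 CPM, Lmod1 at 0.92 (SE 0.08), Notch3 at -1.15 (SE 0.09) and Mcam at -0.56 (SE 0.04). Fibroblast markers rose in 3 of 10 cases and fell in 4 (camera adjusted p = 0.743), with Col1a2 at 1.67 (SE 0.30), Col3a1 at 0.87 (SE 0.08), Fbln1 at -0.89 (SE 0.04) and Col1a1 at -0.50 (SE 0.06). Macrophage and leukocyte markers fell in 4 of 7 cases and rose in 2 (camera adjusted p = 0.280), at low levels such as 3.55 CPM for Cd74, 1.65 CPM for Csf1r and 5.19 CPM for Cd68 in control, with H2-Aa higher at 0.462 against 0.13996 CPM. Neuronal and Schwann cell markers rose in 2 of 8 cases and fell in 1 (camera adjusted p = 0.550), with Tubb3 at -0.58 (SE 0.22). The call of Tubb3 ended without any one library other than control replicate 2, with values of -0.68 to -0.43, and also with no filter on low counts, the replicate block, DESeq2 and the trend on length and GC content removed (adjusted p from 0.0511 to 0.111 in these 4). Adjusted over the list alone, the counts of the first 4 of these lists were the same and those of the last were 1 and 0.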

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

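Halved counts, thinned libraries and the removed trend on length and GC were chosen after seeing the data, and the other alternatives before the data were examined. Genes called numbered from 8401 to 10301 over the alternatives other than glmTreat, against 9495, and 0 of the 9495 were called with the opposite sign in these. Calls with an absolute log2 fold change of at least 1 numbered 277 higher and 585 lower with the filter of 1 CPM, which tests fewer genes, and 171 and 312 with glmTreat, which tests the size itself. Insr was called in each alternative run for single genes, which glmTreat was not. Total-count scaling moved the median of all genes to -0.05 and the share of calls that were higher from 50.03% to 43.7%. With an estimated correlation 0 lists were called higher and 0 lower, and fry called 14 higher. Camera's direction rests on t-statistics with voom weights, and the mean relative to other genes on unweighted log2 fold changes, so their signs can differ. Which members made them differ was not tested. The direction turned for some lists that camera did not call. It turned to higher for ATF4 and CHOP targets, although their mean of -0.105 stayed negative, at -0.0887 with no filter, -0.107 with the replicate block, -0.0755 with the trend removed and -0.117 to -0.0725 with single libraries left out (turned without control replicate 1 or 3 or Circ-INSR siRNA replicate 3). It turned to higher for complexes II to V, from a mean of -0.000556 to 0.0219 with the trend removed and -0.0362 to 0.0477 with single libraries left out (turned without control replicate 3). Without that library it turned to lower for calcium handling genes, whose mean of 0.118 stayed positive at 0.0896 to 0.144. For interferon-stimulated genes, with a mean of 0.105, it turned to higher without Circ-INSR siRNA replicate 3, the highest of -0.121 to 0.362. Of the other comparisons of named genes and lists with the main values, 2597 and 519 kept their direction and their side of the threshold, 16 and 27 lost a call, and 4 lists gained one. Libraries with the same replicate number had correlations of their deviations of 0.02, 0.07 and 0.04. Those with different numbers had -0.044 to 0.006, so each library correlated best with its own number. Whether the numbers mark a small shared effect was not tested and stays open. The block gave 9868 calls, and 98.7% of the 9495 were among them. Alternatives on the share of mitochondrially encoded counts were not run, since no such gene was among the IDs. With counts halved 9287 genes were called, and 9201 of the 9495 were among them.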

Other observations

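ATF4 and CHOP target genes went both ways, with 18 of 41 higher and 13 lower after Circ-INSR siRNA, and 18 and 14 adjusted over the list alone (camera adjusted p = 0.948). The median of the list was 0.04 and its mean -0.15, and camera gave its direction as lower. Gdf15 (-2.15, SE 0.06), Atf3 (-1.33, SE 0.07), Sesn2 (-1.15, SE 0.06) and Ddit3, which encodes CHOP (-0.82, SE 0.05), were lower. Members chosen after their values were seen include tRNA synthetase genes that rose, namely Aars by 0.64 (SE 0.04), Yars by 0.50 (SE 0.04) and Iars by 0.40 (SE 0.05), and the amino acid transporter gene Slc7a5, which rose by 0.49 (SE 0.05). Fgf21 (-2.09, SE 0.20), Chac1 (-1.01, SE 0.14) and Trib3 (-0.50, SE 0.06) fell. The median and mean also differed in sign for interferon-stimulated genes (-0.06 and 0.06), natriuretic and hypertrophy genes (0.02 and -0.01), calcium handling genes (-0.02 and 0.07), fibroblast markers (-0.08 and 0.05) and smooth muscle markers (0.16 and -0.10). For the unfolded protein response, camera gave the direction as higher where median and mean were -0.04 and 0.00.

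Of the tests that follow, those on the exon 2 self-junction, on the same scan in other genes, on shares of base pairs, on the miR-17 family and on Trp53 mRNA were chosen after the results they bear on were seen. In 13613 protein-coding genes with a 3' UTR that could be searched, genes with the 7-base word ACACTTT had a log2 fold change lower by 0.10 than genes without it (-0.10, SE 0.01, z = -6.61), and those with CTGGTAT were also lower (-0.10, SE 0.02, z = -5.85). They were the 2 lowest of 16384 words after CACTTTA (z = -7.65), where 100 shuffles of the genes reached -4.72. Before the terms for length, GC content and expression were removed, z was -2.97 for ACACTTT and -4.07 for CTGGTAT, which ranked 89 and 8 from the lowest, so their place depends on that removal. The highest word was CACTACC (0.15, SE 0.02, z = 7.60; shuffles reached 4.71), which ranked 68 from the highest before that removal (z = 7.23). Of 4169 genes with a site of 7 bases or more of either lower set 33.1% were called lower. The share was 29.9% of all 13613 genes searched and 29.1% of 5746 genes without a site of 6 bases or more of any set. Among the 4072 searched genes called lower 1381 had such a site of 7 bases or more, close to the share of 4169 in 13613. These shares were not corrected for length, GC content or expression.

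The first pattern weighed is that 3' UTR sites ACACTTT and CTGGTAT go with lower values. The length or base composition of the 3' UTR is argued against as the whole cause, since with terms for the shares of all 16 pairs of neighbouring bases removed as well, which moved 145 words by more than 1 in z, z was -6.92 for ACACTTT and -5.49 for CTGGTAT, below the -4.83 that any word reached in 100 shuffles. Sites of 8 bases were lower than sites of 6 bases for ACACTTT (difference -0.215, SE 0.0265) and for CTGGTAT (-0.153, SE 0.0340, computed after the values were seen). The words were picked as among the lowest in these same genes, and 8-base ACACTTT sites also hold the lowest word, CACTTTA. Sites of 6 bases only hold neither word, so that choice favours such a difference, which is no separate evidence for pairing. The grading also does not tell an siRNA from other small RNAs, since sites of the miR-17 family graded nearly as steeply (GCACTTT -0.0326 and GCACTTTA -0.166, against ACACTTT -0.0576 and ACACTTTA -0.204). ACACTTT sites of 7 bases (-0.0505, SE 0.0145) were no lower than sites of 6 bases and A (-0.0640, SE 0.0170). Pairing by an siRNA is a candidate explanation. The 19-base window GAAAGTGTGCCCTGGTATG across the self-junction of exon 2 of Insr (552 bases, mm10 chromosome 8, 3258383 to 3258934, minus strand) has strands whose bases 2 to 8 pair with both words (summed z of -12.5, as for 1 window from exon 9 to exon 2). A junction window as low was held by 2 of 13611 other genes (0.0147%), and by 1 of the 1579 with at least as many windows as Insr. The siRNA sequence is not given in the sources used here, so this stays a hypothesis. Genes with CACTACC sites, a word also picked in these genes, were higher by 0.224 (SE 0.0337) at 8 bases and 0.0752 (SE 0.0169) at 6 bases. Of 1513 genes with such a site of 7 bases or more 41.7% were called higher and 23.5% lower, against 30.4% and 29.1% without a site of any set. CACTACC may likewise mark the control siRNA, which was not tested. MicroRNAs of the miR-17 family cannot be told apart for the ACACTTT sites, since ACACTTT and GCACTTT sites differed by -0.0250 (SE 0.0300).

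Another pattern is that p53 target genes were lower. Direct pairing of their own 3' UTRs through ACACTTT or CTGGTAT sites is argued against by the 13 members with no site of 6 bases or more of either set. They had a median of -0.958 (SE of their mean 0.170), against -0.49 for the 21 members with one. Both words were picked in these genes and only the longest 3' UTR was searched. Pairing through other sites, or in coding sequence, is therefore not covered. Less Trp53 mRNA is argued against as well, since its log2 fold change was -0.01 with a 95% interval from -0.0887 to 0.0672. Scaling does not account for it, since over 4 scalings the median of the list stayed between -0.719 and -0.674. Lower p53 protein or activity, through Circ-INSR or through another effect of either siRNA, stays open and was not tested here, as the design has 1 siRNA against the circular RNA.

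The last pattern is that 9495 genes pass the threshold. Deeper libraries in the Circ-INSR siRNA group are argued against, since 9401 genes were called after thinning to the lowest total. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each count. The real split called 9495 genes, 1418 of them with an absolute log2 fold change of at least 1. The highest of the others called 0 and 0 with edgeR (at most 236 at an unadjusted p under 0.05, against 10200). Camera with the preset correlation called 16 lists in the real split, and 5 to 10 in each other split, where edgeR called 0 genes. Each other split mixes libraries of both groups, so the difference between the groups adds to the spread within each side and lowers its gene calls. These counts therefore cannot decide on chance. A difference in culture or handling between the groups stays open, as the labels give no batch and the replicates are not said to be separate cultures.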
